A study of Mus musculus with 6 samples.

How the data were processed

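Hearts of 3 control mice (L/L in the labels, Elac2 intact) and of 3 knockout mice (L/L with cre) were measured by RNA sequencing. In the knockout, cre expressed from a muscle creatine kinase promoter removed a loxP-flanked exon of Elac2. The mice were on a C57BL/6 background, and total RNA was made into paired-end libraries with a TruSeq kit, per the labels. Technical replicates of each mouse were sequenced, per the series design, and 1 count column per mouse was deposited. Groups and replicate numbers were taken from the sample titles.

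The reads were processed with HISAT2 2.0.5, SAMtools 1.5, featureCounts 1.5.1 and DESeq2 1.16.1 on the mm10 build, per the submitters' processing notes, which give no role or option for each tool. The authors deposited whole-number counts of reads per gene for each library, with no normalisation. The authors also deposited normalised values, a signal in which each library's counts are divided by 1 size factor. The authors' deposited table gives a log2 fold change with its standard error, a test statistic that is a score without a fixed range, and a p-value with its adjusted value for each gene. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The count tables hold 51888 rows, 13 of them features of the mitochondrial genome that carry names in place of Ensembl identifiers. Of the 51875 Ensembl identifiers, 51682 were found in the GENCODE M21 annotation (GRCm38, the same build as mm10), from which coordinates were taken. The 13 mitochondrial features are 11 of mRNAs and 2 of ribosomal RNAs, so mitochondrial tRNAs could not be analysed from these counts.

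Counts were tested as deposited with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, knockout against control, with TMM scaling, the filterByExpr filter with its default minimum count of 10, and no block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values below are from this test unless another tool is named. Levels are CPM, counts relative to the TMM-scaled library size, as mean ± SD over 3 libraries. The SE of a log2 fold change was computed as its size divided by the square root of the F statistic. Where no control library had a read, the fold is a lower bound computed against a floor of 3 counts over the group. Such floors cover counting error only.

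The gene lists were fixed before the data were examined, and 58 of them had members in the count tables. A further list, of mitochondrial tRNAs, had none of its members there. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over 51 lists, and counts of called members are also given as adjusted over the list alone. The estimated correlation and fry were alternatives. The self-contained fry test asks whether a list's genes move and does not compare them with other genes. Shares of counts were compared with a two-sided exact permutation test.

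The rule for named genes was fixed in advance too. It takes Elac2 and each mitochondrial-encoded mRNA and rRNA. It takes the 10 higher and the 10 lower protein-coding genes with the largest absolute log2 fold change among those with adjusted p under 0.05, a mean of at least 1 CPM in the higher group and no overlap of the groups. From each list with a called member it takes up to 4 called members with the smallest adjusted p, and from a list with none called at most 1 member, that with the smallest p. Genes named outside this rule were chosen after their values were seen.

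The test was tried on counts simulated from the means and library sizes of these 6 libraries for the knockout against control comparison, over 13976 tested genes. It recovered 16% of genes changed 1.5-fold, 74% of those changed 2-fold, 94% of those changed 4-fold and 98% of those changed 8-fold, and it called 10 of 13748 unchanged genes. Each fold was given to 50 genes, so far fewer genes were changed than were called in the hearts. The adjusted p depends on that share, so these rates need not hold for the real comparison. Alternatives were RLE scaling, library size alone, TMM without mitochondrial-encoded genes, no filter, a stricter filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a robust fit, each library left out in turn, the replicate number as a block, other thresholds, and the authors' deposited table. TMM without Gm42418 and Lars2 was added after the data were seen. Libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 10.1 for each pair, so each was counted as 1 replicate. Nearly identical nuclear transcripts were sought with blastn, at 95% identity over at least 100 bases for mitochondrial features and 90% for Vmn2r3.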

Results

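The hearts of 3 control mice and 3 Elac2 knockout mice were compared. Elac2 encodes RNase Z, the endonuclease that trims the 3' ends of tRNA precursors in the nucleus and in mitochondria. The labels give cre in the knockout mice and not in the controls. The control libraries held 14276410, 12553384 and 12057962 counts and the knockout libraries 14461110, 13641345 and 9850100 counts.

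Elac2 itself (ENSMUSG00000020549.14, chromosome 11, 64979038 to 65002069 in mm10) fell in the knockout hearts. Its level was 14.0 ± 1.02 CPM in controls and 5.84 ± 0.608 CPM in knockouts (SD, n = 3 each), a log2 fold change of -1.27 (SE 0.15, adjusted p = 2.12e-04), or -0.59 with library size alone (adjusted p = 0.0281). The 3 knockout libraries were at 5.36, 5.63 and 6.52 CPM and the controls at 15.05, 14.00 and 13.01 CPM. The counts cover the whole gene, so reads of the exons that were not removed are included, as are reads of cells without cre.

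The series is about mitochondrial RNAs, and most of those measured fell in the knockout hearts. Mitochondrial-encoded features took 56.3 ± 6.16% of counts in controls and 34.9 ± 1.68% in knockouts (SD, n = 3 each). The groups did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. Of the 11 mRNA features, 7 were lower, 1 was higher and 3 were not called, with a median log2 fold change of -1.56, or -0.83 with library size alone. When adjusted over the list alone, 8 were lower and 1 was higher. The list was lower than other genes with camera (adjusted p = 0.0122), with an adjusted p = 0.672 under an estimated correlation.

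The complex I subunit mRNA mt-Nd6 fell by 2.64 on the log2 scale (SE 0.46, adjusted p = 1.93e-03), and mt-Cytb, of complex III, fell by 2.06 (SE 0.48, adjusted p = 8.14e-03). The size of both falls came mostly from controls 2 and 3. For mt-Cytb these were at 3697 and 6317 CPM and control 1 at 1106 CPM, against 876 to 908 CPM in knockouts. For mt-Nd6 they were at 323 and 633 CPM and control 1 at 121 CPM, against 51.7 to 61.3 CPM in knockouts. The cytochrome c oxidase mRNAs mt-Co1, mt-Co2 and mt-Co3 fell by 1.56, 1.63 and 1.31. The mt-Nd5 mRNA fell from 4664 ± 2895 to 1166 ± 48.5 CPM, and the joint feature for mt-Nd4l and mt-Nd4 fell by 1.64, a call lost without control 2, control 3, knockout 2 or knockout 3 and with limma-voom, a robust fit and the replicate block. By contrast mt-Nd3 was higher by 0.62 (SE 0.22, adjusted p = 0.0466), a call lost without control 1, control 3, knockout 2 or knockout 3 and with the stricter filter. The values of mt-Nd1, mt-Nd2 and the joint feature for mt-Atp8 and mt-Atp6 were -0.84, -0.59 and -1.01 and did not pass the test. All 3 were called lower without control 1 and with no filter, and mt-Nd2 turned to 0.20 with library size alone. For these 3 and for the joint feature of mt-Nd4l and mt-Nd4, control 1 lay below each knockout library. That joint feature was at 1374 CPM in control 1 and at 1518 to 1623 CPM in the knockouts. Both ribosomal RNAs of the mitochondrion fell, mt-Rnr1 by 2.21 (SE 0.45, adjusted p = 4.20e-03) and mt-Rnr2 by 1.32 (SE 0.32, adjusted p = 0.0104), the latter call being lost without control 2. The calls of mt-Co3 and mt-Rnr2 were also lost with library size alone. Of the 13 features 8 share stretches with near-identical annotated nuclear transcripts, so the origin of some of their reads is uncertain. Without these features 3 mRNAs were left, mt-Nd1, mt-Nd6 and mt-Cytb, with a lower median of -2.06, and the list lost its call on these few members (camera adjusted p = 0.146).

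**Figure D1:**
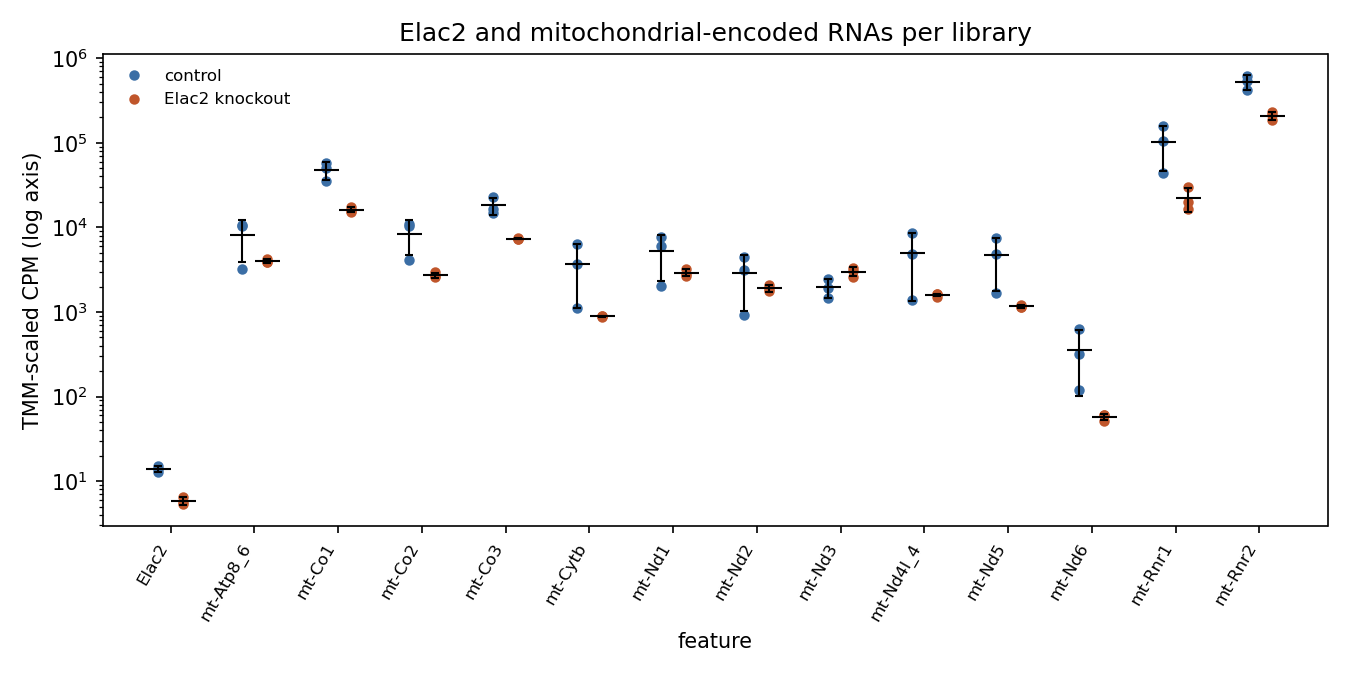
TMM-scaled CPM on a log axis for Elac2 and the 13 mitochondrial-encoded features, with 1 point per library, 3 control and 3 Elac2 knockout libraries, and black bars for mean ± SD. Elac2 was lower in each knockout library than in each control, and mt-Nd3 was the 1 mitochondrial feature called higher, at a log2 fold change of 0.62.

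Genome-wide, 5215 of 14302 tested genes changed with edgeR, 2671 higher and 2544 lower. The split depends on the scaling, since library size alone gave 8093 higher and 552 lower and moved the median log2 fold change of all genes to 0.68, against -0.01 with TMM. Fold changes here are therefore relative to the bulk of tested genes. Library size alone includes mitochondrial-encoded counts, whose share was 34.9% in knockouts against 56.3% in controls. The share left for nuclear genes was thus higher in knockouts. TMM without mitochondrial-encoded genes gave 5235 genes, 2758 higher and 2477 lower, with a median of -0.003 over all genes. The authors' deposited table called 4484 genes, 2352 higher and 2132 lower, and 4295 were called in both, each in the same direction.

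Genes of the integrated stress response, which restrains translation and induces amino acid synthesis, rose. Of 30 tested members 27 were higher and 1 was lower, the same counts as when adjusted over the list alone, with a median log2 fold change of 2.47 (camera adjusted p = 1.40e-17, and adjusted p = 0.323 with an estimated correlation). The secreted stress factor Gdf15 rose from 0.124 ± 0.113 to 115 ± 17.2 CPM. Mthfd2, a mitochondrial folate enzyme, rose by 5.95 (SE 0.21, adjusted p = 3.54e-07), and the asparagine and serine synthesis enzymes Asns and Phgdh by 5.49 and 5.03 on the log2 scale. Genes that respond to load in cardiomyocytes rose as well, 13 of 18 being higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 3.18e-05, and adjusted p = 0.405 with an estimated correlation). The lower members numbered 1 without control 3, knockout 2 or knockout 3. Ankrd1 rose from 197 ± 67.9 to 3280 ± 613 CPM, and the natriuretic peptide gene Nppb from 63.5 ± 13.3 to 700 ± 228 CPM.

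Genes of protein synthesis also rose. Of 80 cytosolic ribosomal protein genes 74 were higher and 1 was lower (75 and 1 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 2.65e-21, and adjusted p = 0.405 with an estimated correlation). Rpl3 rose by 1.76, whereas Rpl3l, its striated muscle paralog, fell by 4.73 (SE 0.21, adjusted p = 1.00e-06). Among 22 ribosome biogenesis factors 19 were higher, also when adjusted over the list alone, Rrp12 by 2.02 and Gnl3 by 1.56 (camera adjusted p = 5.28e-08, and adjusted p = 0.323 with an estimated correlation). Of 22 genes of nuclear RNase P and tRNA processing 12 were higher and 0 lower (13 and 0 adjusted over the list alone), among them Pop4 at 1.22 and the CCA-adding enzyme Trnt1 at 1.21 (camera adjusted p = 2.19e-04, and adjusted p = 0.45 with an estimated correlation). In the list of p53 targets and apoptosis genes 11 of 18 members were higher and 1 was lower (12 and 1 adjusted over the list alone), with Eda2r at 3.20 and Phlda3 at 2.89 (camera adjusted p = 2.15e-04, and adjusted p = 0.323 with an estimated correlation).

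Many genes of fuel oxidation fell. In fatty acid oxidation and uptake 25 of 32 members were lower and 1 was higher, also when adjusted over the list alone (median -0.94, camera adjusted p = 1.04e-07, and adjusted p = 0.529 with an estimated correlation). The electron transfer subunit Etfa fell by 2.04, and Ppara, a nuclear receptor that drives the pathway, fell by 1.55. Branched-chain amino acid breakdown had 13 of 17 members lower, or 14 adjusted over the list alone, including Ivd at -1.81 (camera adjusted p = 4.27e-06, and adjusted p = 0.405 with an estimated correlation). In the tricarboxylic acid cycle 13 of 17 members were lower, or 14 adjusted over the list alone, and 1, Pck2, was higher at 2.06 (camera adjusted p = 1.61e-04, and adjusted p = 0.529 with an estimated correlation). Nuclear subunits of complex I were lower for 14 of 36 members and higher for 0, also when adjusted over the list alone, with Ndufa8 at -0.96 (camera adjusted p = 2.15e-04, and adjusted p = 0.672 with an estimated correlation). Complexes II and III had 8 of 14 members lower, or 9 adjusted over the list alone, with Uqcrfs1 at -1.10 (camera adjusted p = 5.79e-04, and adjusted p = 0.53 with an estimated correlation). With library size alone, the medians of complex I, complexes II and III and the tricarboxylic acid cycle turned to 0.39, 0.20 and 0.05, each still below the 0.68 of all genes, and the complex I call was lost (camera adjusted p = 0.0814), as were those of Ndufa8 and Uqcrfs1. Nuclear subunits of complex IV, cytochrome c oxidase, went both ways, with 5 of 14 lower, or 3 without control 2, and 2 higher, Cox8a at 1.21 and Cox6a1 at 0.83, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.232). The 77 mitochondrial ribosomal protein genes also went both ways, 11 higher, or 7 without knockout 2, and 11 lower, also when adjusted over the list alone.

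Calcium handling and ion channel genes fell for 17 of 22 members, or 18 adjusted over the list alone, and rose for 0 (median -1.07, camera adjusted p = 6.62e-07, and adjusted p = 0.323 with an estimated correlation). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell from 343 ± 29.7 to 36.0 ± 13.2 CPM, and the pacemaker channel gene Hcn4 from 11.0 ± 1.25 to 2.20 ± 0.654 CPM. Cardiomyocyte markers were lower for 5 of 10 members, also when adjusted over the list alone, with Ryr2 at -1.61 and Myh6 at -1.32 (camera adjusted p = 3.93e-03, and adjusted p = 0.323 with an estimated correlation). Endothelial markers were lower for 5 of 11 members, or 6 adjusted over the list alone, including Kdr at -0.96 (camera adjusted p = 0.0194, and adjusted p = 0.405 with an estimated correlation). The endothelial count dropped to 2 without control 2 and without knockout 2, and its list call was lost without control 2 (camera adjusted p = 0.0544). With library size alone, the medians of the cardiomyocyte and endothelial markers turned to 0.15 and 0.36, and the endothelial call and that of Kdr were lost (camera adjusted p = 0.319 for the list). Fibroblast markers had 1 of 10 members higher, or 4 without knockout 1. Macrophage markers had 1 higher and 1 lower of 11, or 2 lower without knockout 3. The counts over all libraries were the same when adjusted over each list alone, and neither list was called. Smooth muscle and pericyte markers had 4 of 10 members lower, with Acta2 at -1.65, and 2 higher, or 1 without control 1, control 2, control 3 or knockout 2, with Cnn1 at 1.41 (5 and 2 adjusted over the list alone). Their median was -0.41, or 0.28 with library size alone, and the list was not called (camera adjusted p = 0.156). The 7 erythroid markers had values from 0.34 to 1.05, with a median of 0.81, and 1, Alas2, was called higher, a call lost without control 1, control 2, knockout 2 or knockout 3, with 0 adjusted over the list alone. That list was not called (camera adjusted p = 0.0921) but was called higher without control 3 (median 1.25, camera adjusted p = 0.0122), without knockout 2 (median 0.95, camera adjusted p = 0.0362), with no filter and with the replicate block. Atrial markers had 1 of 9 members higher, Nppa at 2.58, and 1 lower, Tbx5 at -1.27, also when adjusted over the list alone, and were not called (camera adjusted p = 0.54). Without control 2, 5 were lower and the list was called lower (median -0.90, camera adjusted p = 0.0304), while with library size alone the median turned from -0.56 to 0.14 and the call of Tbx5 was lost. Their levels differed between libraries of a group, and Bmp10, chosen after its values were seen, had 1533, 4 and 1598 counts in controls and 2749, 127 and 1053 in knockouts.

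**Figure D2:**
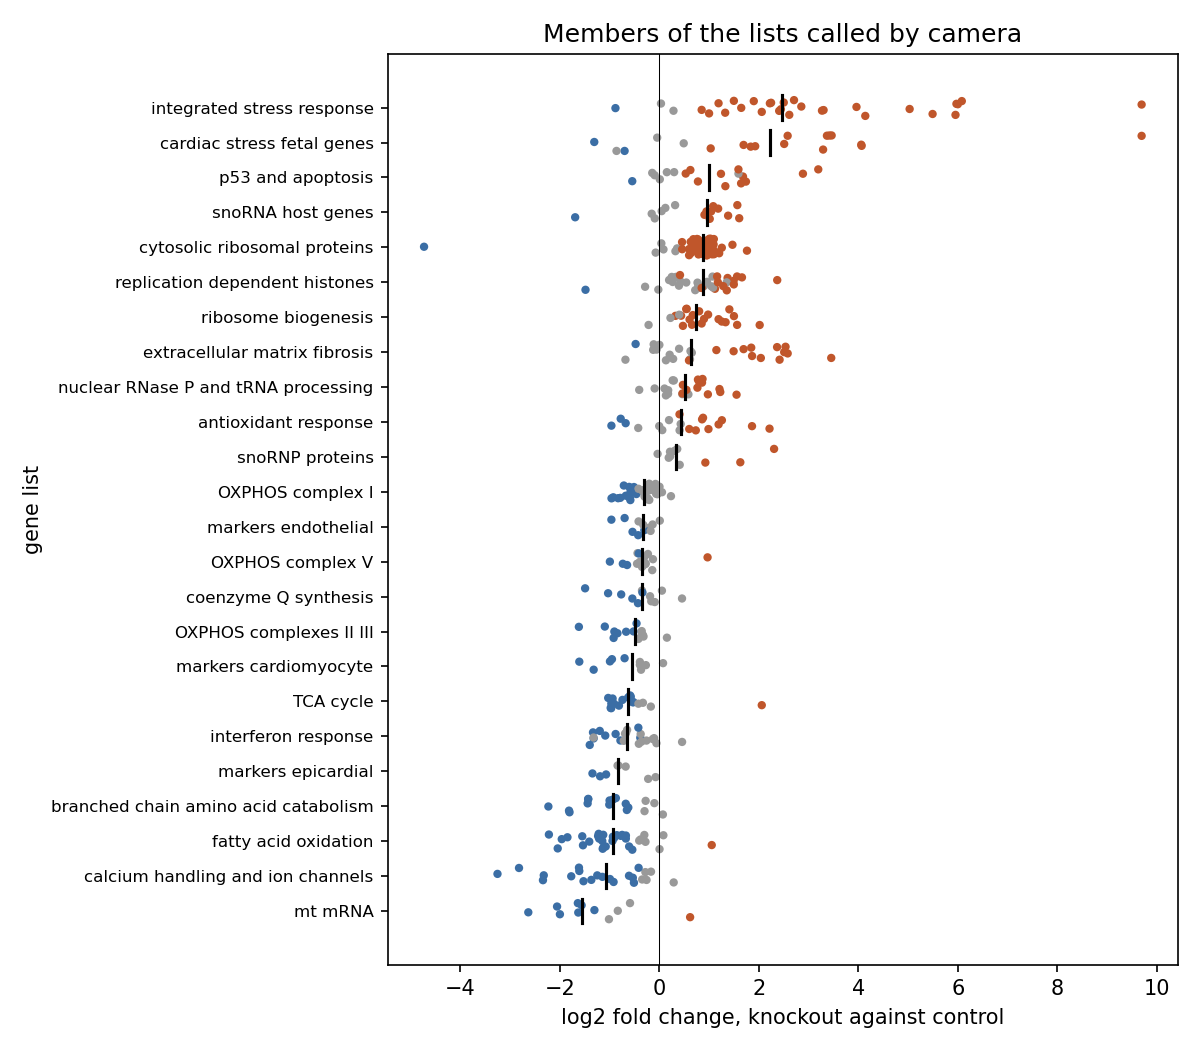
Log2 fold change, knockout against control, of each tested member of the 24 lists called by camera, with 1 point per gene and a black bar at the list's median. Orange points were called higher, blue points lower and grey points neither, with TMM scaling. The integrated stress response has the highest median, 2.47.

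Among non-coding RNAs other than mitochondrial ones, the RNA components of RNase P and RNase MRP, Rpph1 and Rmrp, were higher by 0.87 and 0.86, the former call being lost without control 2. Of 17 small nucleolar and Cajal body RNA genes 5 were higher, or 3 without control 2, control 3 or knockout 3, including Snora73a at 1.11, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.156). Of 8 microRNA genes 3 were lower, or 1 without control 1, control 2 or control 3, and 1 was higher (4 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.117). Counts at these genes are of precursor or host transcripts, not of mature microRNAs. The value for Malat1 was -0.68 (SE 0.24, adjusted p = 0.0488), a call lost without control 1, control 2, control 3, knockout 2 or knockout 3, with TMM without mitochondrial-encoded genes, with the replicate block and with library size alone, where it turned to 0.037.

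The protein-coding genes with the largest fitted rises were Vmn2r3, Gdf15, Acox2, Tnfsf18, B4galnt2, Muc15, Cyb5r2, Nog, 4930438A08Rik and Dthd1. All but Gdf15 had 0 reads in the 3 control libraries, so their order is that of fitted values, and their rises are known only as lower bounds, from 13.9-fold for Dthd1, below the 62.0-fold of Mthfd2. Vmn2r3, a vomeronasal receptor gene (chromosome 3, 64257215 to 64289709), reached 52.6 ± 5.75 CPM and was at least 542-fold higher, and Acox2, a peroxisomal oxidase, reached 7.45 ± 1.81 CPM and was at least 76.7-fold higher. The largest fitted falls were in Lars2, Scn4a, Rpl3l, Slc22a3, Snai3, Clcn1, Efnb3, Gm34302, Wnk2 and Lgi1. Some of these rest on few reads, so their sizes and order are uncertain. Snai3 had 46 counts over the controls and 3 over the knockouts, and Slc22a3 had 64 and 4. The muscle sodium channel gene Scn4a fell by 4.79 (SE 0.27, adjusted p = 3.78e-06). The value for Lars2, -8.54 (SE 2.25, adjusted p = 0.0148), came mostly from control 3 and was -1.07 (SE 0.20, adjusted p = 6.14e-03) without it. Its call was lost without knockout 2 and with a robust fit, limma-voom and the replicate block.

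With 3 mice per group, several calls given above were lost when 1 library was left out, and no library separates cre from the loss of Elac2. All 24 list calls made with the preset correlation were lost with an estimated one.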

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

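The choice of test and of most settings left the counts within 1.5 times: 4420 to 5988 genes changed with RLE scaling, TMM without mitochondrial-encoded genes or without Gm42418 and Lars2 (the last chosen after seeing the data), no filter, a stricter filter, DESeq2, limma-voom and a robust fit. Library size alone gave 8645 genes, 8093 higher and 552 lower, Elac2 at -0.59 (adjusted p = 0.0281) and a mitochondrial mRNA median of -0.83. An adjusted p under 0.01 gave 3006 genes, 1591 higher and 1415 lower, and a log2 fold change of at least 1 gave 1938, 898 higher and 1040 lower. Leaving out 1 library at a time gave 3694 to 5837 genes, 1899 to 2903 higher and 1795 to 2934 lower, Elac2 at -1.35 to -1.21, a mitochondrial mRNA median of -1.73 to -1.36 and 22 to 27 lists. Fewer libraries were tested in these fits. The replicate number as a block gave 4293 genes. Whether the numbers pair the mice is not given in the labels. Deviations of same-numbered libraries correlated at -0.198, 0.085 and -0.087, and of the controls only control 2 correlated best with its own number. With 3 libraries per group these values show no clear pairing but cannot exclude one. An estimated correlation called 0 lists with camera, the smallest adjusted p being 0.323, and fry called 22 by direction and 47 in either direction. By direction, fry did not call complex I, ATP synthase, interferon-response and extracellular matrix genes (fry adjusted p = 0.0665, 0.0656, 0.0665 and 0.113). It called 3 lists that camera did not. The mitochondrial mRNA median, -1.56, lost its call with an estimated correlation (adjusted p = 0.672) and with fry by direction (adjusted p = 0.103), and without the members that have near-identical nuclear transcripts it was -2.06 and also lost its call (adjusted p = 0.146), on fewer members. Camera was not run with DESeq2.

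With library size alone, values turned positive for Ago1 (0.17), Atp5a1 (0.028), Cars2 (0.13), Coq7 (0.14), Dguok (0.089), Fastk (0.13), Flt1 (0.0014), Malat1 (0.037), Sars2 (0.036), Tek (0.26), Tie1 (0.39) and Tnrc6c (0.24), which were called lower with TMM and lost their call, and for the uncalled Csf3r (0.55), Fabp4 (0.26) and mt-Nd2 (0.20). The shift of all genes to 0.68 is larger than each of these. The other turns were in genes and lists not called in either setting, and the cause was not tested. For lists the direction is that of camera, so a median need not turn. Library size alone turned mitochondrial RNA processing (median 0.72), mitochondrial aminoacyl-tRNA synthetases (0.74), microRNA pathway proteins (0.59) and macrophage markers (0.75). No filter turned mitochondrial RNA processing (0.074), mitochondrial synthetases (0.097) and macrophage markers (0.095). The stricter filter turned mitochondrial ribosomal proteins (-0.028) and cell cycle genes (-0.15), and fry turned mitochondrial RNA processing (0.025). Over the fits without 1 library, Csf3r ranged from -0.37 to 0.035, Ptprc from -0.092 to 0.28, mitochondrial RNA processing from -0.028 to 0.081, mitochondrial ribosomal proteins from -0.031 to 0.093, mitochondrial synthetases from -0.021 to 0.13, macrophage markers from -0.029 to 0.14, adipocyte markers from -2.12 to 1.49, sex genes from -0.0080 to 0.086 and immediate early genes from -0.058 to 0.83.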

Other observations

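All tests of explanations here were chosen after the results they bear on were seen, and so were Gm42418, Gm26917, Gm24187, Gm24270, Slc33a1, Vmn2r1, Rnd1, the gene classes and the list of cytosolic aminoacyl-tRNA synthetases with its members. Several further lists moved. Extracellular matrix genes were higher for 13 of 26 members and lower for 1, or 6 without knockout 1, with Tgfb2 at 3.46 and Ctgf at 2.51 (camera adjusted p = 3.52e-03, and adjusted p = 0.672 with an estimated correlation). Antioxidant genes were higher for 10 of 19 members and lower for 3, with Hmox1 at 2.21 and Srxn1 at 1.86 (camera adjusted p = 0.0111, and adjusted p = 0.323 with an estimated correlation). Replication-dependent histone genes were higher for 13 of 34 members, with Hist4h4 at 1.49, and lower for 1, Hist2h2be at -1.49 (camera adjusted p = 2.04e-05, and adjusted p = 0.405 with an estimated correlation), and 6 were higher without control 3. Interferon-response genes were lower for 9 of 22 members, with Oas2 at -1.33 (camera adjusted p = 1.14e-03, and adjusted p = 0.582 with an estimated correlation), and 2 were lower without control 2. With library size alone the interferon median turned to 0.05. Adjusted over each list alone, 15, 10, 14 and 16 members of these 4 lists were called in the stated direction. Host genes of small nucleolar RNAs were higher for 9 of 15 members, with Snhg15 at 1.61, and lower for 1, Snhg14 at -1.69 (camera adjusted p = 3.52e-03, and adjusted p = 0.529 with an estimated correlation), and small nucleolar ribonucleoproteins for 3 of 10, with Nhp2 at 2.31 (camera adjusted p = 9.64e-03, and adjusted p = 0.405 with an estimated correlation). Epicardial markers were lower for 3 of 8 members, with Upk3b at -1.19, a call lost with library size alone (camera adjusted p = 0.0155, and adjusted p = 0.529 with an estimated correlation). Coenzyme Q synthesis was lower for 6 of 12 members, or 3 without control 2 or knockout 3 (camera adjusted p = 0.03, and adjusted p = 0.672 with an estimated correlation) and ATP synthase for 4 of 16, or 2 without control 2 and 7 without control 3, with 1 higher, Atpif1 at 0.97 (camera adjusted p = 0.0122, and adjusted p = 0.672 with an estimated correlation). Adjusted over the list alone, 9, 3, 4, 6 and 7 members of these 5 lists were called in the stated direction, and 1, 0, 0, 1 and 1 in the other. Both the coenzyme Q and the ATP synthase calls were lost without knockout 1 and with library size alone, where the medians turned to 0.35 and 0.36.

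Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and were listed after the data were seen, were higher for 19 of 21 genes, with Sars at 2.65 and Gars at 2.57. Tarsl2 was lower at -0.50 and Qars, at -0.10, was not called. Long non-coding classes of the authors' annotation leaned lower. Among lincRNA genes 73 were lower and 21 higher, and of 134 antisense genes 49 were lower and 9 higher. Processed pseudogenes leaned higher, with 118 of 416 higher and 22 lower. Pseudogenes of ribosomal protein genes, taken over all pseudogene classes, had 31 of 46 higher and 0 lower. Whether reads counted at pseudogenes came from their parent genes was not tested.

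Gm42418, a locus rich in ribosomal RNA sequence, had 236190 counts in control 3 and at most 3996 in any other library. Its log2 fold change was -6.29 (SE 2.11, adjusted p = 0.0409) over all libraries and 1.36 (SE 0.52, adjusted p = 0.0865) without control 3, so its call as lower rests on that library. Carry-over of ribosomal RNA may be the source but stays open, since the neighbouring locus Gm26917 was at 861 CPM in control 3 and at 951 and 641 CPM in the other controls, a log2 ratio of 0.11 to their mean, and was higher in knockouts at 0.98 (adjusted p = 8.39e-03). Gm24187 and Gm24270, annotated as microRNA genes, also stood out in control 3. They had 2568 and 1106 counts there and at most 28 and 12 in any other library. Both were called lower over all libraries (adjusted p = 0.022 and 0.020 with edgeR). Lars2 had the same outlying library, but stayed lower without it at -1.07 (adjusted p = 6.14e-03), which argues against that library as the whole cause of its fall.

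Vmn2r3 had 2541 counts over the knockout libraries and 0 over the controls. A first search for genes that could share its reads matched 1322 genes over a median of 158 aligned bases and decided nothing, and a limit of 3 control counts, added next, could give only 0 genes, since each of the 685 with at least 0.1 of its knockout counts had at least 29 in controls. Had its reads come in a fixed proportion from 1 of the 685, Vmn2r3 would have had at least 160.2 control counts, the value for Rnd1, which argues against these genes as the source but not against a gene whose reads were nearly all assigned to Vmn2r3. A rise of the chromosome region stays open, since the 3 tested genes within 500000 bases had a median of -0.0098 but all lie on 1 side of it, Slc33a1 among them was higher at 0.92, and the nearer, untested Vmn2r1 had 3, 7 and 5 counts in the knockouts and 0 in the controls. By the labels 0 libraries have cre with an intact Elac2, so the transgene and the loss of Elac2 cannot be told apart as its cause.

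The rise of ribosomal protein genes was set against 2 technical explanations. After a length trend fitted on other protein-coding genes was removed, their median was 0.75, against 0.88 before, which argues against gene length as the whole cause. The 46 tested ribosomal protein pseudogenes had a median of 0.93 with 31 higher and 0 lower, which argues against reads moved from them. A response to the loss of Elac2, or to cre, is a hypothesis that stays open.

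The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split with as many as 5215 genes, and the highest of the others had 0 with edgeR. Each of the others mixed control and knockout libraries in both groups, so the difference between genotypes added to the spread within groups. Their 0 therefore does not show what chance alone would give.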
